A study of Oryza sativa with 24 samples.

How the data were processed

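Total RNA of 48 single rice leaves, taken at minutes 1 to 34 and 36 to 49 after noon, was measured on 24 Agilent 2-colour arrays of 45151 spots. Per the labels' protocols, 400 ng of total RNA were amplified and labelled with Cy3 or Cy5. Images were quantified with Agilent Feature Extraction 9.5.3.1, per the file headers, and the deposited spot values are intensity units per the file headers. They are the mean pixel intensity of each spot, the median intensity of its local background, and a processed intensity that Feature Extraction had corrected for background and spatial trend and normalised for dye. A deposited table of log2 signals per locus and channel, called lowess-normalised by its name alone, was also used. How its channels, arrays and probes were combined is not stated, and it was held only in part, up to chromosome 6, with 17932 complete lines. Of its loci 12827 were shared with those kept here, and over shared values the log2 levels correlated at r = 0.983 and the log2 ratios at r = 0.942 (across loci and arrays, which are not independent replicates).

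Values were recomputed from the mean and background intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, ratios were normalised by loess within arrays, and mean levels by quantiles between arrays (Aquantile). Spots of a probe were averaged, a probe was kept if it was well above background in at least 24 of the 48 channels, and each locus was represented by its probe of highest mean level. A locus also needed at most 1 missing array per slide. This kept 30441 probes and 20735 of 29689 loci, of which 6172 had more than 1 kept probe and 7731 no described product. The median signal of an array was 328 to 537 in Cy3 and 689 to 1202 in Cy5, against a median background of 43 to 53 and 50.5 to 55. For 23 kept probes on 2 spots the spot-to-spot SD of the log2 ratio was 0.0254 at the median, against 0.151 between arrays.

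The arrays lay on 6 slides of 4 in order of time (minutes 1 to 8, 9 to 16, 17 to 24, 25 to 32, 33 to 41 and 42 to 49). On each of 3 days 2 slides were scanned, in 7 scans in all. Slide and scan day therefore run with time, position on a slide runs with time within slides, and dye runs with the order of the 2 leaves of a pair. The trend was tested with limma (lmFit, eBayes) on the mean log2 level of both channels of an array, as a slope per hour (60 minutes) with slide as a random block (duplicateCorrelation). A slope per hour extrapolates beyond the 49 minutes sampled. Differences between paired leaves were tested on the log2 ratio of the later to the earlier leaf after removing the mean ratio of each locus, with limma's trended prior for the variance of loci of the same level. The SD between leaves is the SD of the ratio over 24 pairs divided by the square root of 2. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout.

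Gene lists were fixed before the data were examined, 8 as loci and 26 as rules on the descriptions in the array files, and 32 had at least 5 measured members. Of the listed loci 4 were dropped before any value was read, 1 for lack of a probe and 3 because their description named another protein. The rules catch a few other products. The photorespiration rule also matches phosphoglycerate kinase, the cytosolic ribosomal rule a gene described as mitochondrial L16 (Os12g0524700), and the auxin rule a glutathione S-transferase. Symbols of clock, flowering, senescence, DREB and similar genes come from those lists, as the array files do not pair them with loci, and 0 of the kept loci were found by identifier in the reference gene table (assembly ASM3414082v1), so no coordinates are given. Lists were tested for a trend with camera (preset correlation 0.01, estimated correlation beside it) on values whitened by the slide correlation. Variation and correlation within lists were compared with 10000 random lists of the same size matched on decile of level, and correlations between lists with 100000 permutations of the arrays.

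The rule for named genes, also fixed before the data were examined, took all clock genes. It took up to 4 members of every other list that passed a test (those of smallest p in that test's gene-level result). It also took the 10 loci with the largest rise and the 10 with the largest fall among those past the threshold with the same sign within slides, and 15 loci of largest excess variance past the threshold. Loci without a description were to be named at most 2 per direction. As no locus passed for excess variance, the loci of largest variance named as such were chosen after their values were seen.

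Each test was first tested on simulated data. With 200 of 20735 loci given a slope, the trend test recovered 61.5% at a slope of 1 per hour with 15 false calls and 89.5% at 2 per hour with 14 false calls, a share of false calls above the nominal 5%. The gene-level variance test recovered all 200 loci of 3 times the SD when the other loci had equal spread, and 0 of 200 with the spread measured here, so it could not call single loci in these data. The list tests recovered all 8 altered lists each. There the loci were simulated independently of each other, apart from the shared component given to altered lists in the co-variation test. For variation and co-variation the loci of a level also had equal spread. These simulations therefore do not show how the tests of trend and variation act on lists of correlated genes.

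Alternatives tried were the processed intensities, median centring within or between arrays, quantile normalisation of all 48 channels, no filter or a filter in all 48 channels, the mean of all probes and the deposited table. For the trend they were also slide as a fixed block, no block, slide means, single channels, a separate-channel fit, a spline with 3 degrees of freedom, an estimated correlation, and leaving out each array or slide. Added after the data were seen were scan day as a block, spot-to-spot noise as the reference for variance, leaving out the array of lowest Cy5 to Cy3 signal, an estimated correlation in the blocked fits, and removal of channel differences before correlating genes. Control spots and probes without a locus were left out of the comparisons.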

Results

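Leaves of rice (Oryza sativa cv. Norin8) were taken in a paddy field over 49 minutes from noon on 1 day, and gene expression was measured on 24 Agilent 2-colour arrays. The 48 leaves form 1 group, with 1 leaf per minute at 48 time points and no biological replicate at any of them. On every array the earlier leaf was labelled with Cy3 and the later leaf with Cy5, so each array holds a pair of leaves taken 1 minute apart. The labels give the sampling interval as the subject of the series, and the comparisons ask which transcripts moved over the 49 minutes and which differed between leaves taken almost at the same time. The array carried probes for 29689 loci, and 20735 loci passed the signal filter. The share of locus spots well above background ran from 68.7% to 78.9% in Cy3 and from 66.5% to 78.8% in Cy5. For arrays, the number of leaves limits the precision.

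Of the 14 genes of the circadian clock list, 7 passed the test of a slope over the 49 minutes, though none did within slides or with scan day as a block. FKF1 (Os11g0547000) encodes a blue-light receptor F-box protein. It went from a log2 level of 9.93 ± 0.36 (SD, n = 4 arrays) on the earliest slide to 11.75 ± 0.10 (n = 4) on the latest, a 3.54-fold rise. PRR1 (Os02g0618200), a pseudo-response regulator of the evening part of the clock, rose 2.35-fold, from 10.05 ± 0.12 to 11.29 ± 0.08 (n = 4 each), and PRR73 (Os03g0284100) rose 1.66-fold, from 13.55 ± 0.17 to 14.28 ± 0.17. LHY (Os08g0157600), a Myb factor of the morning part of the clock, fell 1.54-fold, from 14.30 ± 0.07 to 13.68 ± 0.15. GI (Os01g0182600, the GIGANTEA homologue) rose 1.43-fold and PRR59 (Os11g0157600) 1.33-fold, whereas ZTL2 (Os02g0150800), another F-box gene, fell 1.26-fold.

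All 14 genes were measured, and with limma's test of the slope per hour 5 rose, 2 fell and 7 did not pass. Adjusted over the list alone, 6 rose and 3 fell, with PRR95 (slope 0.78 per hour) and ZTL1 (-0.36 per hour) added. The slopes were 2.68 ± 0.35 per hour on the log2 scale for FKF1 (SE, n = 24 arrays, adjusted p = 0.000151), 1.79 ± 0.22 for PRR1 (0.000121), -0.99 ± 0.17 for LHY (0.00127), 0.98 ± 0.21 for PRR73 (0.00627), -0.42 ± 0.11 for ZTL2 (0.0229), 0.62 ± 0.17 for GI (0.0231) and 0.49 ± 0.14 for PRR59 (0.0300). The lowest slope among the other probes of the same gene was 1.05 for PRR1 (2 probes), 0.29 for PRR73 (6 probes) and 0.17 for GI (4 probes). The other genes had slopes of 0.68 (LUX), 0.45 (PRR37), 0.39 (ELF3-2), -0.14 (ELF4a) and -0.08 (ELF3-1) and passed neither test. Of the 2 probes of ELF4a the other had a slope of 0.57, of the opposite sign. The 5 probes of PRR37 had slopes from 0.24 to 0.90. The slides held the leaves in order of time, and 2 slides shared each of the 3 scan days. Within slides 12 of the 14 clock genes had the same sign as over the slide means and the slope of GI turned to -0.34 per hour. Those of PRR59 and ZTL2 shrank to 0.07 and -0.04. None of the 14 passed there even when adjusted over the list alone (smallest adjusted p = 0.0686, PRR73). With scan day as a block no clock gene passed (smallest adjusted p = 0.211, PRR73).

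**Figure D1:**
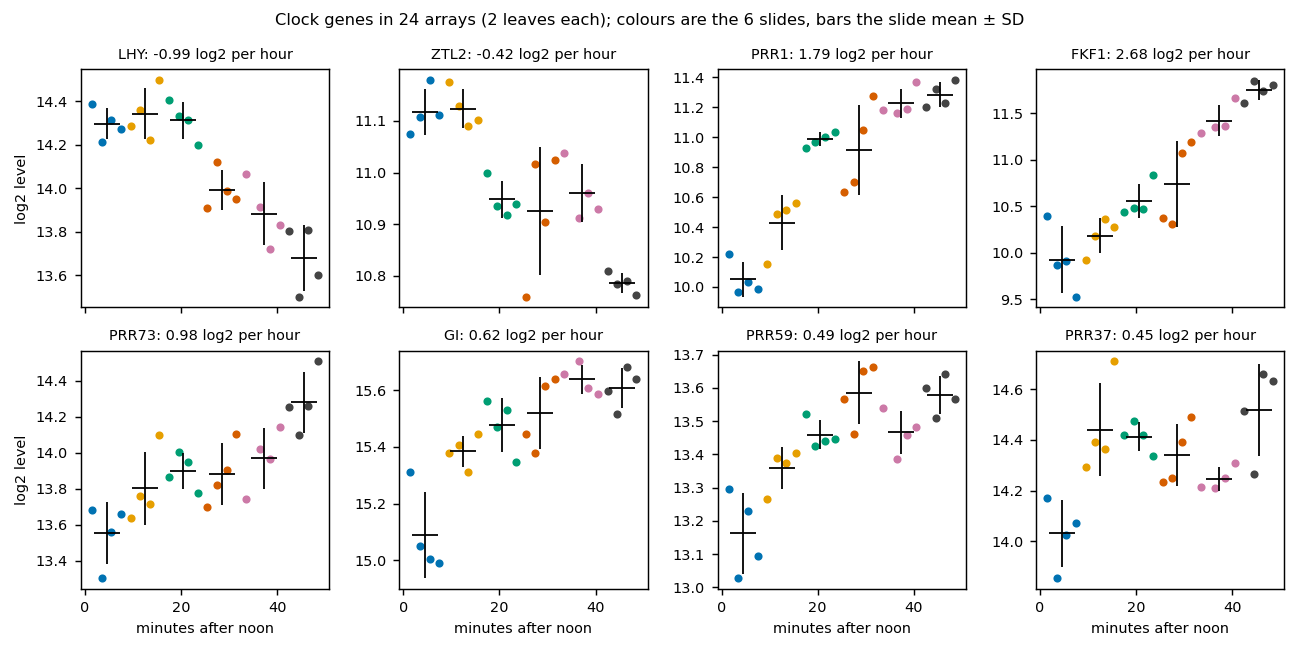
Log2 level of 8 clock genes (y axis) in each of the 24 arrays against the mean sampling time of its 2 leaves in minutes after noon (x axis), with colours for the 6 slides and black bars for the mean and SD of each slide (n = 4 arrays). PRR1 and FKF1 lie lowest on the earliest slide and LHY lies lowest on the latest, while PRR37, with a slope of 0.45 per hour, did not pass the test.

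Over all 20735 loci, 838 rose and 652 fell over the 49 minutes. Among the 10 largest rises were 2 loci with ferredoxin domains, Os07g0489800 (5.34-fold from the earliest to the latest slide) and Os06g0474800 (4.06-fold). Others were the ankyrin repeat locus Os09g0343200 (5.71-fold) and the NADH-dependent glutamate synthase Os05g0555600 (5.14-fold), an enzyme of nitrogen assimilation. FKF1, the RING finger locus Os07g0631200 (2.64-fold), the aldo/keto reductase Os04g0341100 (2.67-fold) and the DnaJ chaperone Os04g0675400 (3.40-fold) followed. The largest fall among loci with a described product was that of Os02g0106100, which the array files describe by likeness to a fructosyltransferase. It fell 5.80-fold, from 14.05 ± 0.67 to 11.51 ± 0.11 (n = 4 each). A second DnaJ chaperone, Os06g0716100, fell 4.67-fold, the multicopper oxidase Os01g0127000 2.40-fold and the KH domain locus Os07g0439100 2.54-fold. The locus of unknown function Os07g0136100 fell 22.6-fold.

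The slopes of these 10 rising loci lay between 2.26 (Os05g0565400) and 3.28 (Os07g0489800) per hour and those of the 10 falling loci between -6.90 (Os07g0136100) and -2.48 (Os05g0344200). Their adjusted p ran from 0.000151 to 0.0132. In all, 1490 of 20735 loci passed limma's test with slide as a random block (slide correlation 0.367), and 4766 had an unadjusted p under 0.05. With slide as a fixed block 72 loci passed (27 of them among the 1490), on the means of the 6 slides 15 passed, and with scan day as a block 4 passed (0 of them among the 1490). Without slide 1, 5 or 6 the count was 661, 389 or 508. With arrays centred on their median instead of quantile scaling, 1555 passed but with 572 rising and 983 falling, so the balance of rises and falls rests on the scaling.

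Of the 47 measured genes for proteins of the plastid ribosome, 15 rose and 0 fell (22 and 1 adjusted over the list alone, 0 in all within slides), and the list's median slope was 1.83, -0.14 and 0.20 per hour on the 3 scan days. They included the 50S proteins L14 (Os05g0292600, 1.89-fold), L13 (Os01g0749200, 1.62-fold) and L34 (Os01g0805000, 1.58-fold) and the 30S protein S15 (Os02g0803200, 1.30-fold). Genes of the proteasome, which degrades ubiquitin-tagged proteins, went the other way: 6 of 41 fell and 1 rose (8 and 1 adjusted over the list alone, 0 in all within slides). The 6 falls included 1.47-fold for RPN6a (Os03g0576400), 1.25-fold for RPN2a (Os08g0224700, slope -0.46 per hour, but -0.19 with another of its 3 probes) and 1.18-fold for RPT4a (Os06g0607800). The gene that rose, 1.25-fold, was a homologue of regulatory subunit 6A (Os04g0284600), which was dim at a level of 7.60. In phenylpropanoid and flavonoid synthesis, the route to lignin and flavonoid pigments, 3 of 36 genes fell and 1 rose (10 and 1 adjusted over the list alone, 1 in all within slides). The leucoanthocyanidin dioxygenase-like gene Os05g0127500 fell 3.46-fold and the 4-coumarate-CoA ligase genes Os01g0901500 and Os03g0152400 fell 1.57-fold and 1.23-fold. Within slides the slopes of the first 2 genes were 1.47 and 0.20 per hour, of the opposite sign. The gene that rose was the chalcone synthase family member Os11g0529500 (1.24-fold). For the phenylpropanoid and flavonoid list the median slope was -2.57, 0.74 and -0.44 per hour on the 3 scan days.

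Lists were compared with all other loci by limma's camera test with a preset correlation of 0.01, and 7 of 32 passed. None of the 7 calls holds with an estimated correlation (adjusted p = 0.678 for each). The plastid ribosomal list (median slope 0.38 per hour, adjusted p = 9.02e-07), chlorophyll and carotenoid synthesis (0.37, 0.00525), the circadian clock (0.47, 0.0354) and photosystem subunits (0.18, 0.0290) were shifted upwards. The proteasome (median slope -0.21 per hour, adjusted p = 6.54e-05), phenylpropanoid and flavonoid synthesis (-0.77, 7.45e-05) and jasmonate synthesis with its JAZ repressors (-0.81, 0.000770) were shifted downwards. Arrays 3, 4, 13 and 14, with the leaves of highest jasmonate gene level, stood apart on the largest axis (principal component) of array levels. Their values were 42.7, 34.7, 57.2 and 40.7, against at most 6.98 for the other arrays, on an axis with 29.4% of the variance. With median centring between arrays the median slope of the photosystem list was 0.03, that of the plastid ribosomal list 0.18 and that of the proteasome list -0.38. In the chlorophyll list 1 of 23 genes rose (uroporphyrinogen III synthase, Os03g0186100, 1.22-fold) and 0 adjusted over the list alone. In the photosystem list 1 of 26 rose under both adjustments (a PsbQ-type gene of the oxygen-evolving complex, Os07g0105600, 2.01-fold). None of the 28 jasmonate genes passed on its own under either adjustment: the JAZ (ZIM domain) genes Os09g0439200 and Os07g0615200 had slopes of -2.42 ± 0.83 and -1.88 ± 0.59 per hour (adjusted p = 0.0750 and 0.0524). The jasmonate list's median slope was -3.07, 1.89 and -0.43 per hour on the 3 scan days. On those days it was 0.965, 0.007 and 0.075 for the chlorophyll list and 0.278, 0.024 and -0.001 for the photosystem list. For the clock list it was 0.995, 0.156 and 0.517, and for the proteasome list -0.780, -0.391 and -0.181.

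With slide as a fixed block the plastid ribosomal (adjusted p = 0.0490), proteasome (0.0151) and phenylpropanoid (0.0211) lists passed and the clock (0.4), photosystem (0.886), chlorophyll (0.244) and jasmonate (0.244) lists did not. With scan day as a block the proteasome (6.96e-07) and plastid ribosomal (0.00317) lists passed. Cytosolic ribosomal proteins (156 genes, 3 rose) passed upwards and senescence and chlorophyll breakdown (6 genes, 0 passed) downwards in those blocked fits (adjusted p = 0.0151 and 0.0490 within slides) but not in the reported fit. With processed intensities the first of them passed (0.0400) and the second did not (0.221). With an estimated correlation (0.748 and 0.616 for these 2 lists within slides) no list passed in either blocked fit, and both had an adjusted p of 0.978 within slides and 0.966 with scan day as a block. The median slope of the cytosolic ribosomal genes, 0.11 per hour, turns to -0.06 with median centring between arrays.

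The other lists did not pass the camera test. Aquaporins (8 genes, median slope -0.40 per hour), glutathione S-transferases (47 genes, 3 fell, -0.42) and WRKY factors (55 genes, 1 rose and 2 fell, -0.22) had an adjusted p of 0.0560, and with processed intensities the glutathione S-transferases passed (0.0362). Heat shock proteins (76 genes) held 4 genes that rose and 4 that fell, and calcium sensors (71 genes) 3 and 1. Light-harvesting proteins (16 genes, 1 rose), the Calvin cycle (22 genes, 0 passed), photorespiration (25 genes, 1 rose) and antioxidant enzymes (36 genes, 4 rose) had adjusted p values of 0.347, 0.347, 0.347 and 0.299. Of 61 cell cycle genes 3 rose and 1 fell, of 42 histone genes 1 rose and 1 fell, of 47 ethylene response factors 1 rose and 2 fell, and of 30 genes of starch and sucrose metabolism 2 rose and 1 fell. A single gene rose among 49 auxin response genes, 20 wax and cuticle genes, 8 nitrate assimilation genes and 5 phytochrome and cryptochrome genes each. A single gene fell among 18 cell wall loosening genes and 62 pathogenesis related genes each. No gene passed in the lists for dehydration and ABA response (8 genes), flowering time (9), seed storage proteins (20) and pollen and anther (6). The last 2 had a positive median slope but a negative camera direction. Adjusted over the list alone, the counts were 0 risen and 4 fallen for aquaporins, 5 and 1 for antioxidant enzymes, 2 and 3 for glutathione S-transferases, 1 and 1 for WRKY factors, 4 and 1 for the cell cycle, 4 and 0 for photorespiration, 2 and 2 for starch and sucrose metabolism and 1 and 0 for cytosolic ribosomal proteins. In the other lists of this paragraph they were the same as over all loci.

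The trend over minutes could not be separated from differences between slides. Across loci, which are not independent replicates, the slope within slides and the slope over the 6 slide means had a Pearson r of 0.350. An exact permutation test over the 720 orders of the slides gave p = 0.335 (2-sided). Without array 13, which holds the leaves of minutes 25 and 26, the same exact test gave p = 0.00417. Neighbouring arrays of a slide differed by a mean square of 0.0867 and other arrays of the same slide by 0.105, a ratio of 0.824 that did not pass a permutation test of the order within slides (2-sided p = 0.384).

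Among the lists tested, leaves taken a minute apart differed most in genes of phenylpropanoid synthesis and of jasmonate synthesis and signalling. Each leaf was labelled once, so these differences also hold any difference in RNA preparation and labelling. The SD between the leaves of a pair was 0.136 on the log2 scale for the median locus, whereas the median of the 28 genes of jasmonate synthesis and JAZ proteins was 0.450 and that of the 36 phenylpropanoid and flavonoid genes 0.459. The JAZ gene Os10g0392400 had an SD of 1.07 (n = 24 pairs), or 0.566 without its farthest pair, and log2 ratios of the later to the earlier leaf, relative to its mean ratio, from -6.08 to 1.77. The chalcone synthase gene Os07g0526400 had an SD of 1.29, the WRKY gene Os09g0417600 0.853 and the beta-1,3-glucanase gene Os01g0713200 0.919. Of the genes that loosen cell walls, the expansin gene OsEXPA2 (Os01g0823100) had an SD of 1.17 and the xyloglucan endotransglucosylase gene Os06g0697000 1.16. In the senescence list NAP (Os03g0327800, a NAC factor) had 0.863 and SGR (Os09g0532000, the stay-green gene of chlorophyll breakdown) 0.517. Among the flowering genes MADS14 (Os03g0752800) had 0.649, but 0.207 with another of its 6 probes.

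Against 10000 random lists matched on level, 20 of 32 lists varied more and 1, the proteasome, less. The median log2 excess of variance, relative to loci of the same level, was 3.93 for jasmonate (random lists 0.341), 3.80 for phenylpropanoid and flavonoid, 3.28 for senescence, 3.00 for pathogenesis related, 2.98 for WRKY and 2.82 for wax and cuticle genes. It was 2.71 for dehydration and ABA response, 2.69 for chlorophyll and carotenoid synthesis, 2.40 for cell wall loosening, 2.34 for flowering time and 2.27 for photosystem genes. It was lower, but still past the threshold, for seed storage (1.91), light-harvesting (1.91), glutathione S-transferase (1.85), nitrate assimilation (1.77), ethylene response factor (1.62), plastid ribosomal (1.27), auxin response (1.21), histone (1.11) and heat shock (0.98) lists. It was -0.93 for the proteasome. The smallest unadjusted p, 1e-04, is the smallest that the random lists can give (2-sided test against random lists of loci). Adjusted p for the 21 lists ran up to 0.0468 (nitrate assimilation). The clock list, with 0.12, did not pass (p = 0.646, adjusted p = 0.714). The test drew loci at random and not leaves, so it treats the members of a list as independent. Members differed together between leaves (mean pairwise r 0.354 for jasmonate and 0.499 for senescence genes). These p values can therefore be too small, and they do not measure the sampling of leaves.

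No single gene passed the test of excess variation: limma's trended prior had 2.38 degrees of freedom, 1099 loci had an unadjusted p under 0.05, and the lowest adjusted p was 0.876. A prior without robust estimation also gave 0 loci (1133 at an unadjusted p under 0.05). The loci named here were therefore the most variable of their lists, and their SDs carry no gene-level call.

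Genes of photosynthesis differed between paired leaves as a block. The 16 light-harvesting genes had a mean pairwise r of 0.695 over the 24 pairs (-0.0025 for the median random list). In single leaves their mean level ran from -0.79 at minute 2 to 0.68 at minute 4, relative to the mean of each dye. The largest spread was that of Os01g0720500 (chlorophyll a-b binding protein 2, SD 1.47), and CP24 (Os04g0457000) had an SD of 0.575. Photosystem subunits (mean r 0.498), with the photosystem II 10 kDa gene Os07g0147500 at an SD of 1.05, and the genes of chlorophyll and carotenoid synthesis (0.335), with protochlorophyllide reductase A (Os04g0678700) at 0.820, did the same. In the Calvin cycle list (0.190) the Rubisco small subunit gene Os12g0274700 had an SD of 0.941. The 156 cytosolic ribosomal protein genes had the highest mean r, 0.709, with a median SD of only 0.148, and the proteasome genes had 0.494 at a median SD of 0.0813.

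In all, 24 of 32 lists passed this test (1-sided, 10000 random lists matched on level, smallest possible p 1e-04). Like the test of variation it drew loci and not leaves, so its p values do not measure the sampling of leaves. The others that passed were senescence (0.499), wax and cuticle (0.375), jasmonate (0.354), histones (0.336), phytochrome and cryptochrome (0.334), plastid ribosomal (0.246), cell wall loosening (0.225), WRKY (0.222), pathogenesis related (0.163), circadian clock (0.141), seed storage (0.140), phenylpropanoid and flavonoid (0.122), glutathione S-transferases (0.0890), heat shock (0.0714), cell cycle (0.0668), ethylene response factors (0.0531), calcium sensors (0.0491) and antioxidant enzymes (0.0464). Aquaporins, auxin response, dehydration and ABA response, flowering time, nitrate assimilation, photorespiration, pollen and anther, and starch and sucrose metabolism did not pass (adjusted p from 0.0641 to 0.440).

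**Figure D2:**
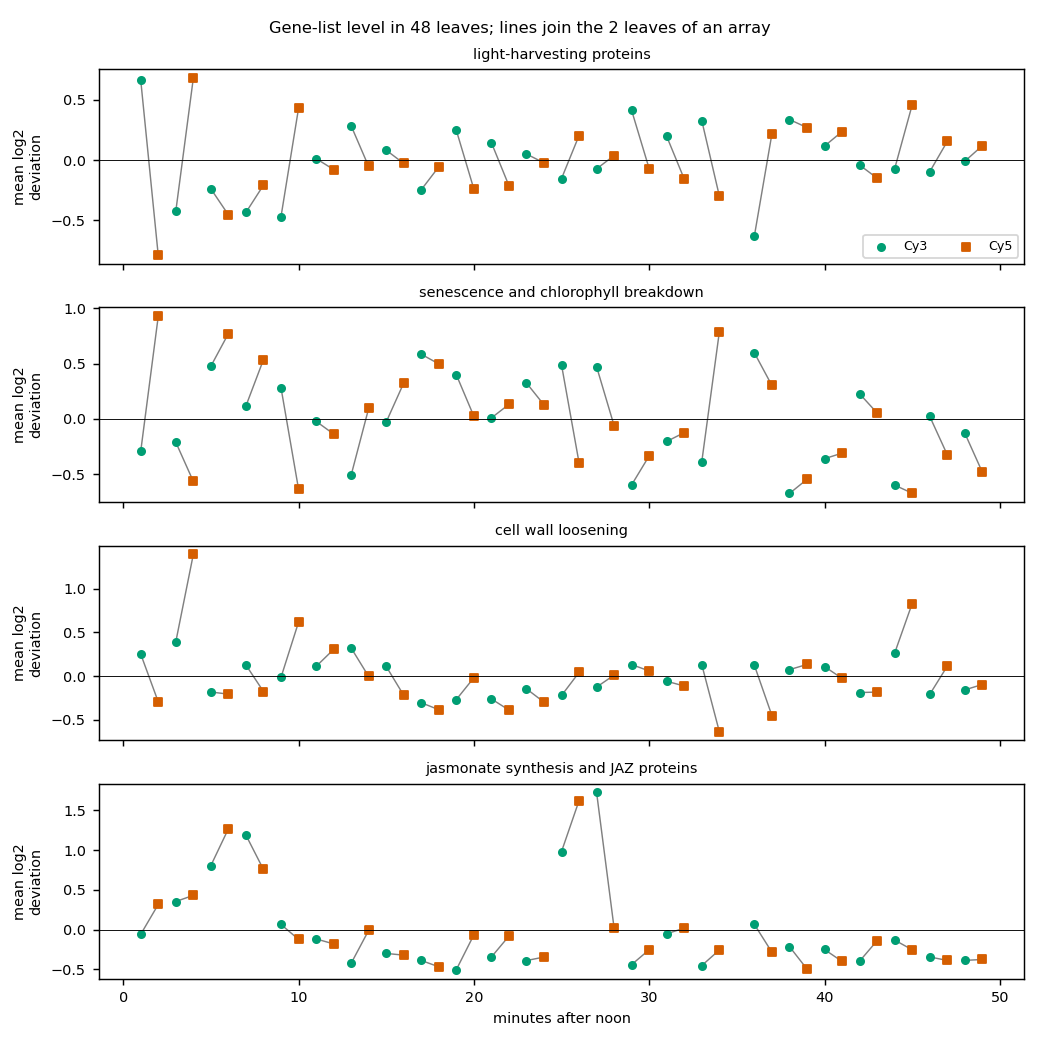
Mean log2 deviation of the genes of 4 lists (y axes) in each of the 48 leaves against minutes after noon (x axis), relative to each gene's mean in the same dye, with circles for Cy3, squares for Cy5 and a line joining the 2 leaves of an array. The jasmonate list is highest at minutes 26 and 27 (1.62 and 1.73) and the light-harvesting list lowest at minute 2 (-0.79).

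Across pairs of leaves, some lists went together and others in opposite directions. Over all loci, 36.6% of the variance of the log2 ratios lay on 1 axis (principal component) and 14.5% on the next. The correlations between lists were not compared with those of random lists. Whether a relation is particular to its lists or part of such a shared axis was therefore not tested. Leaves with more light-harvesting transcript than their partner had more photosystem transcript (r = 0.946, rho = 0.946, same sign in 23 of 24 pairs) and more plastid ribosomal protein transcript (r = 0.938, rho = 0.890). Leaves with a higher mean of the Calvin cycle list had a higher mean of the photorespiration list (r = 0.936, rho = 0.929). The photorespiration genes did not correlate among themselves past the test against random lists (mean r 0.0193, adjusted p = 0.185). Their rule also matches phosphoglycerate kinase, so this relation need not hold for photorespiration genes at large. Proteasome genes ran against photosystem genes (r = -0.916, rho = -0.841). Genes of senescence and chlorophyll breakdown ran against the Calvin cycle (r = -0.873, rho = -0.824). Cell wall loosening went with wax and cuticle (r = 0.855, rho = 0.923) and wax and cuticle with the cell cycle (r = 0.855, rho = 0.858). Calcium sensors went with ethylene response factors (r = 0.914, rho = 0.735) and WRKY factors with glutathione S-transferases (r = 0.830, rho = 0.820).

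Of the 495 pairs of lists that share no gene 159 passed a permutation test of Pearson's r (2-sided, adjusted over all pairs), 104 positive and 55 negative. By rank 168 passed, and 128 passed by both. For the pairs named above the permutation p of r was 1e-05, the smallest that 100000 permutations can give (adjusted p = 0.000118), and that of rho was at most 1e-04 (adjusted p at most 0.000952). On the 3 scan days (n = 8 pairs each) r was 0.970, 0.906 and 0.943 for light-harvesting with photosystem genes, -0.914, -0.815 and -0.954 for proteasome with photosystem genes, and -0.930, -0.797 and -0.902 for senescence with the Calvin cycle. It was 0.978, 0.767 and 0.936 for light-harvesting with plastid ribosomal genes, 0.964, 0.848 and 0.974 for the Calvin cycle with photorespiration, 0.839, 0.922 and 0.903 for cell wall loosening with wax, 0.914, 0.881 and 0.923 for the cell cycle with wax. It was 0.818, 0.984 and 0.873 for calcium sensors with ethylene response factors, and 0.824, 0.945 and 0.844 for WRKY factors with glutathione S-transferases. The 2 pairs of leaves farthest from the median of 1 of the 2 lists were then left out, without regard to the other list. There r lay between 0.776 and 0.905 for the positive relations and was -0.851 and -0.864 for the negative ones. WRKY factors and jasmonate genes also passed (r = 0.812, rho = 0.590, p = 3e-04 and 0.00317, adjusted p = 0.00209 and 0.0152). Without the 2 pairs farthest from the median of the WRKY list r was 0.434, so much of that relation rests on those pairs. On the 3 days it was 0.418, 0.915 and 0.697.

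**Figure D3:**
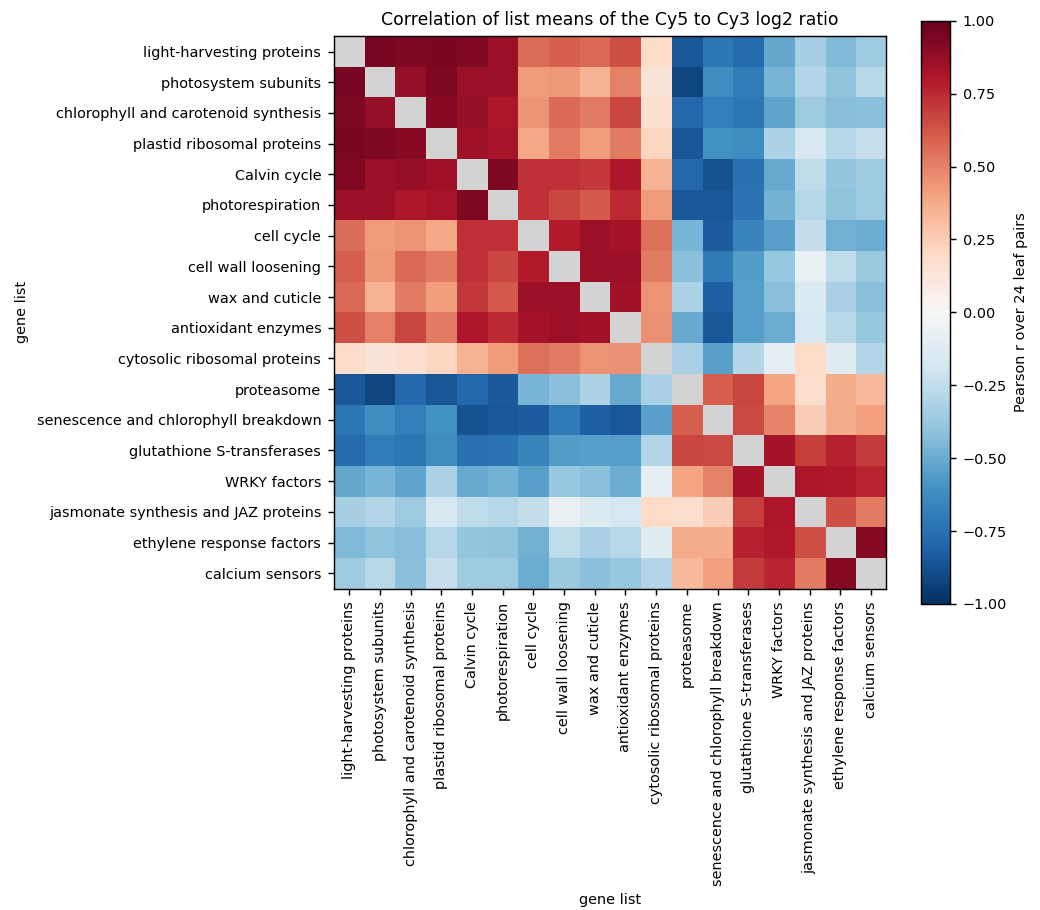
Pearson r, over the 24 pairs of leaves, between the mean log2 ratios of 18 gene lists (both axes), with red for positive and blue for negative r and grey for a list with itself. Light-harvesting, photosystem and plastid ribosomal lists correlate positively (r = 0.946 for the first 2), and the proteasome list negatively with them (r = -0.916 with photosystem subunits).

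A 1-minute difference in a fixed direction could not be separated from dye. The later leaf of each pair was always in Cy5, and 3566 loci had a higher and 3198 a lower level in Cy5 than in Cy3 (limma, 6764 of 20735 loci, median size of the log2 ratio 0.138 among them). With median centring instead of loess within arrays 14651 loci passed, 12033 of them higher in Cy5. These counts hold the dye effect of each probe together with any effect of the minute, and no gene is named from them.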

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

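The tests that set slopes within slides against slopes over slide means, of the order of scan days, of 8 of the 16 light-harvesting genes at a time, those that use random lists of loci and those that remove channel differences were chosen, as evidence on technical causes, after the result was seen. The test of slide order, and a test of light-harvesting genes with different descriptions, were written before their results were seen. After the results were seen, the explanation tested with random lists was reworded and its bounds were changed. The bound by which removing channel differences moves too little to count as a test was also set then, and it changed the reading of that test from against the explanation to open. The test of 8 genes at a time replaced the test by description, which left out only 4 of 120 pairs of genes, so that its mean r of 0.710 could not have been under 0.685.

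A signal lay in probes that no comparison used. Of 588 probes without a locus, 80 (13.6%) were well above background in at least 24 of the 48 channels, against 0 of 153 negative control spots.

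The time trend of 1490 loci was weighed against slide, scan day and chance. Of 100 orders of the 6 slides only the real order gave as many loci as it did, 1 of 100. This argues against a chance order only if the 6 slides are exchangeable. The real order gave 1488 loci with the slide correlation taken from 1 in 10 loci, against a median of 0 for the others. Another order gave 1095 at most, and in it the last 2 slides, which share a scan day, were exchanged. Slides of a scan day need not be exchangeable with others, and the 3 days have 6 orders, too few for a share under 0.05: the real order of the days gave 1488 loci and the highest other 272. Differences between slides or scan days cannot be told apart from time: slopes within slides, free of both, resembled the slopes over slide means no more than under other orders of the slides (exact p = 0.335), and with scan day as a block 4 loci passed. With array 13 left out, the exact p of that likeness was 0.00417. With slide as a fixed block 72 loci passed, 27 of them among the 1490, but there position on a slide runs with time. Time of day, the biological explanation that the design gives, stays open.

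For the clock genes the slopes within slides and over slide means had r = 0.786 across the 14 genes, which are not independent replicates. An exact permutation of the slide order gave p = 0.128, which leaves slide or scan day open. A likeness of these slopes shared by loci at large stays open too: 6.16% of random lists of 14 loci matched on level reached it, with a median r of 0.457. Time of day is the biological explanation the design gives, and it was not separated from the slides. In single leaves the clock list was lowest at minute 27 (mean log2 deviation -0.335, relative to each gene's mean in the same dye). In that leaf the jasmonate list was highest (1.725). Whether the slopes of the clock genes rest on such differences between leaves was not tested.

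Photosynthesis and jasmonate genes differed together between paired leaves. A difference in labelling or signal between the channels stays open. With the raw signal ratio and the difference in detected share removed, the mean r was 0.681 against 0.695 before for light-harvesting genes, against 0.0722 for the 95th percentile of random lists, and 0.348 against 0.354 for jasmonate genes, against 0.0366 for that percentile. These 2 measures were linked to the ratios of only 14 of 20735 loci (adjusted p under 0.05) and removed 9.49% of the variance of the median locus, against 6.39% by chance, so their removal moves too little to test the explanation. On the 3 scan days (n = 8 pairs each) the raw signal ratio had r = 0.006, -0.106 and -0.735 with the light-harvesting list. With the jasmonate list it had r = 0.192, -0.059 and 0.773. A few near-identical copies are argued against as the whole cause of the light-harvesting block: over all 12870 ways to keep 8 of the 16 genes the lowest mean r was 0.480, against 0.141 for the 95th percentile of random lists of 8. Binding of many probes of that family to the same transcripts was not tested. No biological explanation was tested, since the labels give no group such as leaf age, position or plant.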

How the results depend on the processing

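Scan day as a block, an estimated correlation in blocked fits and spot-to-spot noise as the reference were chosen after seeing the data. For loci with a time trend, 1490 passed in the reported fit. The count was 72 with slide as a fixed block, 15 on the means of the 6 slides, 4 with scan day as a fixed block, 343 in the Cy3 channel alone, 5880 with no slide block and 6060 in a separate-channel fit with no slide block. The 2 fits without a block treat the arrays of a slide as independent and the slide means leave 6 values, and the cause of the other moves was not tested. The remaining alternatives, apart from those that leave out an array or slide, gave 1131 (spline) to 1972 loci (Cy5 alone), and loess against median centring within arrays cannot move the mean of both channels. On the loci that the deposited table holds, 976 passed here and 954 with the deposited values. Leaving out 1 array or slide gave 389 to 2007 loci with a trend, an r of the 2 slopes of 0.144 to 0.446 (past its threshold without array 13 alone, exact p = 0.00417), and a similarity ratio of 0.714 to 1.07. It gave 0 loci with excess variation each time and 4721 to 7348 loci with a dye difference. Leaving out 1 array, the only leave-outs run for lists, gave 20 to 23 lists with excess variation and 23 to 26 with co-variation. Lists with a trend numbered 7, against 0 with an estimated correlation, 4 with scan day as a fixed block, 5 with slide as a fixed block (0 in either with an estimated correlation) and 9 with processed intensities. Excess variation went from 0 to 20467 loci against spot-to-spot noise, because that reference leaves out all differences between leaves and labellings. Loci with a dye difference went from 6764 to 14651 with median centring instead of loess, and the cause was not tested. With slide as a fixed block 3 slopes of named genes that passed in the reported fit reversed: GI to -0.34, Os01g0901500 to 0.20 and Os05g0127500 to 1.47 per hour, none past the threshold (ELF3-1, which had not passed, went from -0.08 to 0.06), and the cause was not tested. Correlated pairs of lists numbered 159, against 171 with processed intensities and 158 with median centring. Without the filter on signal over background, which adds dim loci to the test, 1957 loci had a trend. There r of the 2 slopes was 0.268, against 0.350 in the reported fit.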

Other observations

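The correlations with DREB genes and with the raw signal ratio, and the test of neighbouring arrays, were chosen after the result was seen.

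The 7 leaves of highest jasmonate gene level lay in 2 stretches of the series. They were on arrays 3 and 4 of slide 1 and arrays 13 and 14 of slide 4. Leaves of 1 array share its mean level, so these leaves are not independent values. Minute 28, the partner of minute 27, was at 0.018. The list mean was 0.805, 1.27, 1.19 and 0.757 at minutes 5 to 8 and 0.982, 1.62 and 1.73 at minutes 25 to 27, against a lowest value of -0.50 at minute 19 (SD 0.558 over 48 leaves). WRKY factors (1.31) and ethylene response factors (0.667) were also highest at minute 27. Across the 24 pairs the jasmonate list correlated with DREB2A (Os01g0165000, a dehydration-responsive factor) at r = 0.829 and rho = 0.561 (permutation p = 0.00011 and 0.00511, 6 relations computed, adjusted p of r = 0.00066). This r was 0.676 without the 2 pairs farthest from the median of the jasmonate list, and 0.691, 0.892 and 0.693 on the 3 scan days (n = 8 each). DREB1B (r = 0.375), DREB1A (0.365) and DREB2B (-0.386) did not pass (adjusted p = 0.137 each). None of the 4 measured DREB genes had a trend (adjusted p from 0.395 to 0.965). Nor had the sucrose transporter gene SUT1, the 1 measured gene of the list for secondary cell wall and vascular tissue (0.34 ± 0.22 per hour, adjusted p = 0.365). The raw signal ratio of the channels did not pass with the light-harvesting list (r = -0.157, rho = -0.0157, permutation p = 0.464 and 0.944). Nor did it with the jasmonate list (r = 0.140, rho = 0.110, permutation p = 0.501 and 0.610). On the 3 scan days r was 0.006, -0.106 and -0.735 for the light-harvesting list and 0.192, -0.059 and 0.773 for the jasmonate list.

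Other loci of largest leaf-to-leaf variance, named after their values were seen, were a SAM-dependent carboxyl methyltransferase (Os02g0719600, SD 1.57), an O-methyltransferase (Os10g0118200, 1.54), a bHLH factor (Os04g0301500, 1.5), a UDP-glucosyltransferase family member (Os10g0442300, 1.38), a ribonuclease T2 (Os09g0537700, 1.25) and an aminotransferase-like gene (Os01g0238500, 1.17), each over 24 pairs. Of 20735 loci 770 had an SD over 0.5 and 40 over 1. On the first scan day the median slope of the histone genes was -1.49 per hour and on the third 1.86.

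One hypothesis is that leaves taken close in time may share their level of jasmonate genes. Neighbouring arrays of a slide differed by 0.337 times the mean square of other arrays of the slide (permutation p = 0.0858, 2-sided), which leaves it open. Of the 32 lists tested in the same way none passed after adjustment, the smallest p being that of histones (0.00879, adjusted p = 0.281).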
